A study of Homo sapiens with 6 samples.

How the data were processed

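RNA from 6 human cultures of a placental or a choriocarcinoma line was measured, each on a single Affymetrix HG-U133 Plus 2.0 array with biotinylated cRNA and 1 colour. The deposited values are log2 signals per probe set, and RMA is named, without a version, in the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a probe set. The sorted values of the 6 arrays lay close to each other and were not identical. RMA evens out the arrays before it summarises the probes, so this is no sign of a later step. No later step by the authors is given in the sources used here. Array medians were 6.51 for 3A-Sub E, 6.49 for NP-R7, 6.54 for JEG-3, 6.57 for JEG-3-R7, 6.51 for JEG-3-R6 and 6.57 for JEG-3-R5, in log2 units.

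The value table held 54613 probe sets. The platform annotation gave 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Of the probe sets with 1 symbol, 41037 were matched by gene ID to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. XIST, TSIX and genes of chromosome Y were left out, which removed 59 probe sets and left 41032, for 19740 genes. Each gene took the value of its probe set with the highest mean over the 6 arrays. The gene table served only to name genes and to tell which genes are neighbours, and no coordinates were used. No probe set is named DHFR in the annotation used, so DHFR, the target of methotrexate, was not analysed here. Unnamed probe sets are given only as counts.

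Groups were taken from the labels, with 1 array in each of 6 groups. Pairs of arrays were therefore compared by their log2 difference without a test. A gene was counted as 2-fold or more higher or lower when the absolute log2 difference was 1 or more and the brighter array of the pair had a log2 signal of 6 or more. The number of arrays limits the precision, and a pair has no replicate check. Genes were ranked by difference, and the text names the 8 highest and 8 lowest genes of a pair, up to 4 members of each gene list with the largest absolute difference, and always TYMS, SLC19A1, FPGS, GGH, ABCC1, ABCG2, ABCB1 and MSH3. For genes that moved one way at every step of selection the 5 with the largest total rise and the 5 with the largest total fall were eligible, and for genes shared by both lines the 8 each way with the largest smaller difference. For model fits the 10 genes each way with the lowest p were eligible. Symbols of uncharacterised loci were not named, and another probe set of a named gene that went the other way by over 0.5 is mentioned. The comparisons, thresholds, naming rule, gene lists and alternatives were chosen before the data were examined. Lists whose medians lay inside the range of random lists are given mainly as counts or medians.

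The 23 gene lists were folate and antifolate transporters, folate enzymes, neighbouring genes of chromosome 5, purine synthesis, pyrimidine and deoxynucleotide synthesis, trophoblast hormones, trophoblast identity, epithelial, mesenchymal and stromal, endothelial, leukocyte and macrophage, proliferation, senescence and cytokine genes with cyclin-dependent kinase inhibitors, p53 targets, DNA repair, apoptosis, interferon response, amino acid and protein folding stress, hypoxia and glycolysis, cholesterol synthesis, xenobiotic and NRF2 response, WNT, TGF-beta and BMP response, and housekeeping. They held 456 entries, of which 413 were measured. The symbol DDX58 was looked up under its current name, RIGI. The median of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these arrays only.

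Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) to 15214 genes whose highest array had a log2 signal of 6 or more. A fit of all 6 arrays held cell line and resistance as terms, with 3 residual degrees of freedom, and a further fit added their product, with 2. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 3 JEG-3 sublines come from a single selection series and the arrays of a line come from a single culture, so they are not independent replicates and the p-values are too small. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the figures.

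The code was tested on simulated data. With 200 genes changed among 15214, the resistance term recovered 59% of them at a log2 change of 1, 97.5% at 2 and 100% at 4, with 6, 11 and 15 false calls. The term for the difference between lines recovered 0%, 26% and 99.5%, with 0, 7 and 21 false calls. Every array was given independent noise and every changed array the same change, unlike the real sublines. These shares therefore hold for that setting only. In a simulated pair of arrays with no change, 224 of 15214 genes differed 2-fold or more, with a spread taken from the limma fit, which holds differences among the sublines. In 200 unchanged lists, 9 lay outside the middle 95% of random lists.

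Comparisons that share the parental JEG-3 array were set beside 100 simulated draws of unchanged sublines against that array. Runs of neighbouring genes that were all 2-fold or more higher were set against 10000 shuffles of the gene order, and medians over windows of 25 neighbouring genes against 1000 shuffles. Alternatives were no signal floor, a floor of 7, the mean of all probe sets of a gene, leaving out probe sets marked as able to take signal from related transcripts, cyclic loess between arrays (3 iterations), a 3-fold threshold, other filters and variance priors in limma, other sets of arrays and leaving out each array. Cyclic loess shifted no array median by over 0.05.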

Results

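Transcript levels were measured in a placental and a choriocarcinoma cell line and in sublines of them selected for growth in methotrexate. This drug is an antifolate used against gestational trophoblastic neoplasia. 3A-Sub E is a benign line of term placental cells immortalised with SV40, and JEG-3 is a clonal choriocarcinoma line. Cells were passaged in rising methotrexate and stocks were frozen at each log concentration, while the parents were passaged alongside without drug. NP-R7 is the 3A-Sub E subline resistant to 0.1 µM, and the JEG-3 sublines are JEG-3-R7 (0.1 µM), JEG-3-R6 (1 µM) and JEG-3-R5 (10 µM). Each of the 6 cultures was measured on 1 array, so no difference between a pair of arrays has a replicate check or a test, and genes are described as higher or lower. All differences are on the log2 scale, where 1 is a 2-fold difference, and any difference between a pair of arrays of which the dimmer is below a log2 signal of 6 is set against background and is to be read as a minimum size. Between 58.1% and 59.5% of probe sets had a log2 signal of 6 or more on each array. Across genes, which are not independent replicates, the values of the parents correlated at r = 0.8826. The r of NP-R7 with 3A-Sub E was 0.9857, and with JEG-3 it was 0.9878 for JEG-3-R7, 0.9843 for JEG-3-R6 and 0.9916 for JEG-3-R5.

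The parental lines were compared first, to describe how JEG-3 differs from 3A-Sub E before any drug. The lines carried markers of different cell types, so their differences cannot be ascribed to malignancy. JEG-3 carried epithelial and trophoblast transcripts that were low in 3A-Sub E, and 3A-Sub E carried stromal matrix and cytokine transcripts that were low in JEG-3. Among the genes furthest apart, those higher in JEG-3 included KRT19, an epithelial keratin (10.24), PEG3, a paternally expressed imprinted gene (9.95), CDH1, which encodes E-cadherin (9.77), CGA, the common alpha subunit of the glycoprotein hormones (9.64), NLRP2 (9.02) and LIN28A, a repressor of let-7 microRNAs (8.85), with S100P (8.84) and CPVL (8.79). Those lower in JEG-3 included DKK1, a secreted WNT antagonist (-9.85), FSTL1 (-9.42), GREM1, a secreted BMP antagonist (-9.01), ABI3BP (-8.92) and the proteoglycan gene SRGN (-8.72). NNMT (-8.48), THBS1, which encodes thrombospondin (-8.16), and the collagen gene COL8A1 (-8.05) were among them. For 15 of these 16 genes the dimmer array was below a log2 signal of 6, so these are minimum sizes with no settled order. The same holds for 8 of the 16 genes named first in JEG-3-R7, 7 in JEG-3-R6 and 3 in JEG-3-R5. In all, 1583 genes were 2-fold or more higher in JEG-3 and 2079 lower, of 14685 above the signal floor.

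Of 26 trophoblast identity genes, 21 were higher in JEG-3 and 1 lower, with a median difference of 4.47. They included XAGE2 (7.70), the transcription factor of syncytial differentiation GCM1 (6.95), VGLL1 (6.60) and the homeobox gene DLX6 (6.39), all below 6 in 3A-Sub E and so minimum sizes. Of 16 epithelial genes, 14 were higher and 0 lower (median 5.14), among them the adhesion molecule EPCAM (7.16) and RAB25 (6.47). Of 24 mesenchymal and stromal genes above the floor, 0 were higher and 19 lower (median -3.58), with COL3A1 at -7.60, COL6A3 at -7.45, vimentin (VIM) at -7.32 and POSTN at -7.09. With the mean of all probe sets of a gene in place of the brightest, these 3 medians were 3.19, 3.51 and -3.18. The senescence and cytokine list had 1 member higher and 11 lower of 17 (median -2.82), including the interleukin genes IL6 (-6.09), CXCL8 (-5.71) and IL1B (-5.64). Among 16 p53 targets 9 were higher and 1 lower (median 1.57), with SESN1 at 3.65, GDF15 at 3.42 and PHLDA3 at 2.99. The hormone list was split, with 7 members higher and 8 lower of 27. The steroid synthesis genes HSD3B1 and CYP19A1 stood at 6.88 and 5.38.

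For the genes of antifolate handling, the efflux pump ABCG2 was higher in JEG-3 (3.90), as was the proton-coupled folate transporter SLC46A1 (2.01). The efflux pumps ABCC4 (-1.89) and ABCC1 (-1.19) were lower, as was GGH, which removes glutamates from folates and methotrexate (-2.02). GLDC, of the glycine cleavage system, was at 6.61, and thymidylate synthase (TYMS), SLC19A1 and FPGS were at -0.69, 0.30 and 0.16. Of the other lists, purine synthesis had 0 members higher and 3 lower (median -0.39, PRPS2 at -3.07) and pyrimidine synthesis 3 and 5 (-0.24). Proliferation had 1 and 2 (-0.51, with CCNE1 at 4.15), DNA repair 1 and 4 (-0.48, with the alkyltransferase gene MGMT at 4.33) and apoptosis 2 and 6 (-0.45). Interferon genes had 1 and 6 (-0.37), amino acid stress genes 7 and 0 (0.62, ATF3 at 3.90), hypoxia genes 4 and 2 (0.24), cholesterol genes 2 and 0 (0.57) and WNT and TGF-beta genes 4 and 4 (-0.08). The chromosome 5 list had 6 and 3 (0.37), the folate enzymes 1 and 1, endothelial markers 1 and 0 (0.12) and leukocyte markers 1 and 1 (0.32). Xenobiotic genes had 5 and 4, with a median of 0.33 and a mean of opposite sign, -0.28. Housekeeping genes had 0 and 0, and a second probe set of B2M went the other way (0.51 against -0.30).

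All 6 arrays were then fitted together with limma, with cell line and resistance as terms, so that the line difference could be set against the spread among arrays. At an adjusted p under 0.05, 2761 genes were higher and 3194 lower in the JEG-3 arrays. KRT19 was higher by 10.08 (SE 0.13, limma adjusted p = 9.81e-07), CDH1 by 9.86 (SE 0.14) and PEG3 by 10.16 (SE 0.16), with the germ-cell gene GTSF1 (8.52), TRIM71 (8.02) and LIN28B (6.82) also among the lowest p. DKK1 stood at -9.57 (SE 0.17, limma adjusted p = 1.09e-06), followed by EMP1 (-7.82), FSTL1 (-9.10) and CKLF (-7.73). Apart from LIN28B, each of these genes was below 6 in the dimmer line, so the fitted differences are set against background and their order is not settled. Over all genes, 21 of 26 trophoblast identity genes were higher and 1 lower (22 and 1 adjusted over the list alone), 15 of 16 epithelial genes were higher (16 adjusted over the list alone), and 17 of 24 mesenchymal genes were lower (20 adjusted over the list alone). The arrays of a line are sublines of a single culture, so these p-values are too small. Without the NP-R7 array the count was 3477.

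NP-R7 was set against 3A-Sub E to describe resistance to 0.1 µM in the benign line. Among the genes furthest above 3A-Sub E were the neutrophil chemokines CXCL5 (5.83) and CXCL1 (4.39), interleukin-1 alpha (IL1A, 4.53) and PTGS2, the inducible cyclooxygenase (4.4). IL1A and CXCL1 belong to the senescence and cytokine list, and CXCL5 and PTGS2 to no list used here. NAP1L3 (4.55), the mannosidase gene MAN1A1 (4.48), ADGRL2 (4.29) and the transcription factor SOX7 (4.05) were also among the highest. The lowest were MSTN, which encodes the growth inhibitor myostatin (-4.65), the adhesion molecule VCAM1 (-4.40), SEMA3E (-3.71), SUSD5 (-3.63) and the stearoyl-CoA desaturase SCD (-3.43), then the sodium channel gene SCN9A (-3.34), ZNF140 (-3.31) and the inhibin subunit INHBB (-3.15). For 12 of these 16 genes the dimmer array was below 6, so their differences are minimum sizes and have no settled order. In total 395 genes were 2-fold or more higher and 268 lower, of 14222.

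The senescence and cytokine list had 9 members higher and 0 lower of 19, and its median of 0.75 was at percentile 100 of the random lists. The matrix protease MMP3 (3.53) and CXCL8 (3.17) were in it. Of 16 p53 targets 3 were higher and 0 lower (median 0.58), namely the repair factor DDB2 (1.39), ZMAT3 (1.25) and GDF15 (1.12), and the death receptor FAS stood at 0.92. Amino acid stress genes had 2 higher and 0 lower of 20 (median 0.35), ATF3 at 1.53 and XBP1 at 1.08, but the other XBP1 probe set above the floor was at -0.1. No cholesterol synthesis gene passed 2-fold, with 0 higher and 0 lower of 14, and their median was -0.34, at percentile 0.11 of the random lists. MSMO1 was at -0.86, NSDHL at -0.84, INSIG1 at -0.84 and STARD4 at -0.78. Mesenchymal genes had 2 higher and 5 lower of 24 (median -0.17), with LUM at -2.72, COL3A1 at -2.33, POSTN at 2.31 and ACTA2 at 1.65. WNT and TGF-beta genes had 2 higher and 1 lower of 17 (median -0.24), with the activin subunit INHBA at 2.07, WNT5A at 1.33 and SMAD6 at -1.79.

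GLDC was higher by 1.81 and was the single folate enzyme past 2-fold. No folate transporter passed it, and SLC19A1, the reduced folate carrier, was at 0.18, ABCC1 at 0.15 and ABCG2 at 0.26. TYMS was at 0.03, FPGS, which adds glutamates to methotrexate, at 0.52, GGH at -0.31 and MSH3 at 0.11. ABCB1 was below a log2 signal of 6 on each of the 6 arrays. In the trophoblast identity list GATA3 (-2.30) and PEG10 (1.84) stood out, and in the apoptosis list BCL2A1, which restrains cell death (2.54). Medians were 0.12 for purine synthesis, -0.02 for pyrimidine synthesis, 0.07 for DNA repair, -0.10 for proliferation, 0.13 for interferon, -0.12 for hypoxia, 0.27 for xenobiotic genes, 0.07 for epithelial genes, 0.14 for hormones, 0.05 for endothelial markers, 0.06 for leukocyte markers and -0.05 for housekeeping genes. Second probe sets went the other way for PPAT (-0.59 against 0.52), CFLAR (-0.69 against 0.80) and PDK1 (-0.85 against 0.46). Without probe sets that can take signal from related transcripts, ADGRL2 was at -0.18 and SMAD6 at 0.17.

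JEG-3-R7 was set against JEG-3 to describe the same level of resistance in the choriocarcinoma line. Interferon response genes were higher in JEG-3-R7, among them IFI27 (5.31), IFIT2 (4.55) and IFIT1 (4.22). DDX60 (4.29) and IFIH1, a sensor of double-stranded RNA (4.09), which are in no list used here, were among the highest too. The fibrillar collagen gene COL3A1 (4.84), MARCKS, a protein kinase C substrate (4.42), and CARD16, a regulator of caspase-1 (4.4), were among the 8 highest as well. The lowest were MGST1, a microsomal glutathione transferase (-5.28), the cancer-testis genes MAGEA4 (-4.42), MAGEA6 (-3.71) and MAGEA12 (-2.81), and the WNT receptor gene FZD10 (-2.87). TEX30 (-2.70), the mitochondrial reductase DECR1 (-2.65) and CASD1 (-2.61) followed. MAGEA genes are close copies of each other, and their probe sets can share signal. In all, 359 genes were 2-fold or more higher and 134 lower, of 14377.

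Of 18 interferon genes above the floor, 16 were higher and 0 lower, with a median of 2.98. IFIT3 was at 4.06. A group of 5 genes of chromosome 5, neighbours among the genes that reach a log2 signal of 6 on some array, was also higher. They were the mismatch repair gene MSH3 (2.30), RASGRF2 (3.62), the mitochondrial creatine kinase CKMT2 (3.89), CKMT2-AS1 (3.95) and ZCCHC9 (2.94), and the nearest such genes on either side, ZFYVE16 and SSBP2, were at 0.23 and 0.49. Genes between ZFYVE16 and MSH3 were not analysed here, and ACOT12, between ZCCHC9 and SSBP2, was below 6 on every array (0.30 in JEG-3-R7), so the exact edge was observed on neither side. A run this long occurred in 1 of 10000 shuffles of the gene order (one-sided permutation p = 0.0002). Both MSH3 probe sets, at 2.30 and 1.46, are marked as able to take signal from related transcripts, so MSH3 is the least certain member of the run. In JEG-3-R6 the same 5 genes stood at -0.27, 0.20, 0.82, 0.75 and 0.68, and in JEG-3-R5 at -0.32, 0.36, 0.60, 0.05 and -0.20. The whole chromosome 5 list had 3 members higher and 0 lower of 19, with a median of 0.06. No DNA was measured, so copy number is not known.

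**Figure D1:**
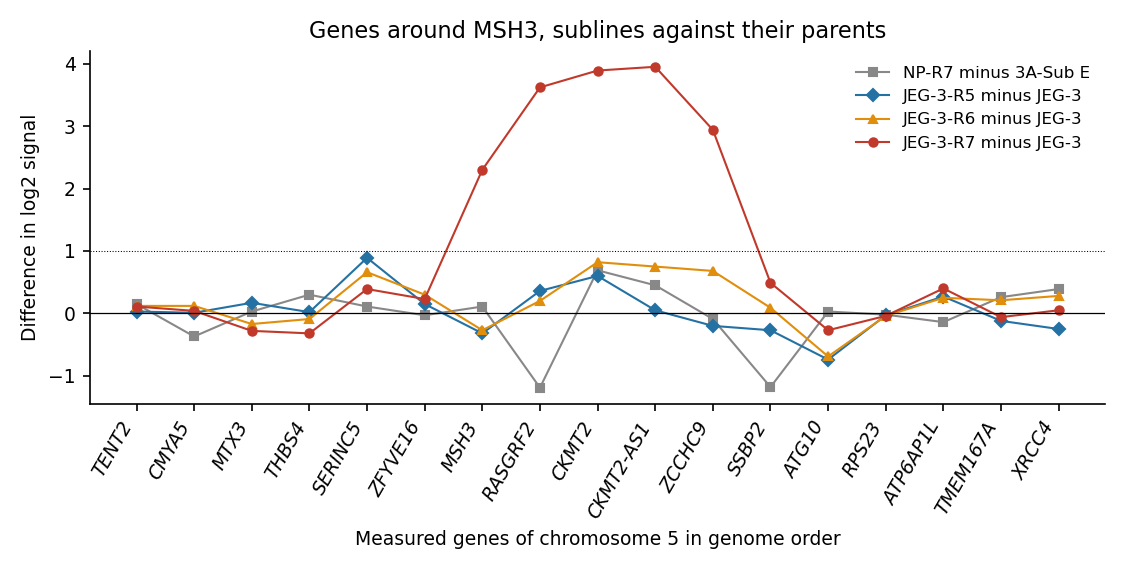
Log2 difference of each subline from its parent (vertical axis) for neighbouring chromosome 5 genes in their order along the chromosome (horizontal axis), 1 array each, with a dotted line at a 2-fold difference. In JEG-3-R7 the genes from MSH3 to ZCCHC9 lie between 2.30 and 3.95, and ZFYVE16 and SSBP2, the nearest genes on either side that reach a log2 signal of 6 on some array, at 0.23 and 0.49.

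Folate transporters had 0 higher and 1 lower of 11 in JEG-3-R7 (median -0.24), with the efflux pump ABCC4 at -1.92 and ABCC1 at 0.97. DHFR2, a paralogue with dihydrofolate reductase activity, was at 1.49, but another of its probe sets was at -0.81. The probe set at 1.49 is marked as able to take signal from related transcripts, so it may not measure DHFR2 alone. TYMS was at -0.09, SLC19A1 at -0.15, FPGS at -0.03, GGH at 0.14 and ABCG2 at -0.38. Trophoblast identity genes had 3 higher and 2 lower of 26 (median 0.24), with ENDOU at 1.59, the fusogenic envelope gene ERVFRD-1 at 1.58 and XAGE3 at -1.85. Hypoxia genes had 2 higher and 1 lower of 19 (median 0.23), NDRG1 at 1.33 and the lactate dehydrogenase gene LDHA at -1.59. Xenobiotic genes had 3 higher and 0 lower, including CYP1A1 (1.64) and HMOX1 (1.59), with a median of -0.17 and a mean of 0.05. In the WNT list ID1 was at -1.57 and SMAD7 at -1.51, and in the mesenchymal list SNAI2 at 1.91. In the senescence and cytokine list the kinase inhibitor CDKN2B was at 1.65, but its other probe set above the floor was at 0.17. The proliferation median was -0.17, cholesterol -0.20, purine synthesis -0.07, p53 targets 0.12, epithelial genes 0.02 and leukocyte markers -0.07.

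JEG-3-R6, resistant to 1 µM, had the most genes apart from JEG-3 among the sublines. The highest were MARCKS (5.95), IFIT2 (5.47), CARD16 (5.06), COL3A1 (4.92) and SNAI2, a transcription factor of epithelial-mesenchymal transition (4.26), followed by IFIT3 (4.22), IFIH1 (4.04) and DDX60 (3.91). The lowest were MAGEA4 (-4.64), MGST1 (-4.16), MAGEA6 (-3.30), FZD10 (-2.59) and the embryonic globin gene HBE1 (-2.55), then MAGEA12 (-2.51), ANXA3 (-2.34) and SEC14L4 (-2.24). Of 27 hormone genes of the placenta above the floor, 11 were 2-fold or more higher too. Those furthest apart were genes of pregnancy-specific glycoproteins. In all, 645 genes were 2-fold or more higher and 117 lower, of 14392.

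Interferon genes had 14 higher and 0 lower of 16 in JEG-3-R6, with a median of 2.48 (2.11 with the mean of all probe sets). Hormone genes had 11 higher and 0 lower of 27 (median 0.54), with PSG9 at 2.86, PSG5 at 2.69, PSG3 at 2.58 and PSG6 at 2.51. Other probe sets of PSG9, PSG5 and PSG6 above the floor moved less, the lowest by 0.40, 0.08 and 0.05. The PSG genes are near-identical copies, and their probe sets can share signal. Mesenchymal genes had 6 higher and 0 lower of 18 (median 0.13), with TWIST1 at 2.18 and COL5A2 at 1.61. Epithelial genes had 2 higher and 0 lower of 16 (median 0.09), with ELF3 at 1.41 and SPINT1 at 1.05, so the epithelial list did not fall. Purine synthesis genes had 0 higher and 0 lower of 13, with a median of -0.40 at percentile 0.03 of the random lists, APRT and PFAS both at -0.77. P53 targets had 3 higher and 0 lower of 16 (median 0.52), GDF15 at 1.70 and DDB2 at 1.33. The cyclin-dependent kinase inhibitors CDKN2B and CDKN1C were at 3.73 and 1.74, but the other CDKN2B probe set above the floor was at -0.06. Trophoblast identity genes had 5 higher and 2 lower of 26 (median 0.27), with ENDOU at 2.63, ERVFRD-1 at 1.82 and HAND1, a transcription factor of trophoblast giant cells, at -1.39. In the xenobiotic list AKR1C3 was at 2.34, CYP1A1 at 2.15, HMOX1 at 1.74 and the glutathione transferase GSTA4 at -1.64, and LDHA was at -1.91. ABCC1 was at 1.02, ABCC4 at -1.36, TYMS at -0.04, SLC19A1 at -0.17, FPGS at -0.11, GGH at -0.47 and ABCG2 at 0.32. The proliferation median was -0.06, that of leukocyte markers -0.17 and that of amino acid stress genes 0.17. Other probe sets of CFLAR ranged from -1.08 to 1.06, against 0.50 for the brightest.

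JEG-3-R5, resistant to 10 µM, had fewer genes apart from JEG-3. The highest were MME, a membrane endopeptidase (2.53), MARCKS (2.28), ERVFRD-1 (2.28), DOCK4 (2.28), PSG9 (2.19) and ENDOU (2.19), followed by SH3TC2 (2.08) and RGS2, a regulator of G-protein signalling (2.08). The lowest were MAGEA4 (-3.19), HAND1 (-2.79), PHACTR1 (-2.10), the immune checkpoint ligand VTCN1 (-1.96) and CXADR (-1.92), then COL12A1 (-1.78), CHAC2 (-1.73) and PODXL (-1.72). Other probe sets above the floor moved far less for some of these genes. The lowest were at 0.03 for MARCKS, 0.28 for PSG9 and 0.75 for DOCK4, and the highest of PHACTR1 was at 0.29. In all, 228 genes were 2-fold or more higher and 82 lower, of 14318. With the mean of all probe sets of a gene the total was 196. The simulated pair with no change had 224 of 15214 genes 2-fold or more apart, counting both directions. Its spread may be too wide, but part of the genes counted in each subline may be noise.

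Hormone genes had 8 higher and 0 lower of 27 in JEG-3-R5 (median 0.71), and trophoblast identity genes 7 higher and 1 lower of 26 (median 0.33), with the fusogenic envelope gene ERVW-1 at 1.40. Among the hormone genes, PSG5 (1.92) and PSG6 (1.79) had other probe sets above the floor as low as 0.16 and -0.0. Interferon genes had 6 higher and 0 lower of 15, with a median of 0.37, IFITM1 at 1.88, IFIT2 at 1.75, IFI6 at 1.63 and BST2 at 1.17. Hypoxia genes had 2 higher and 0 lower of 19 (median 0.38), with NDRG1 at 1.53, ENO2 at 1.07 and ADM at 0.92. Purine synthesis genes had 0 higher and 1 lower of 13 (median -0.37, percentile 0.11), with PRPS1 at -1.03 and HPRT1 at -0.53. The stress genes DDIT4 (1.71) and DDIT3 (1.16) were the 2 amino acid stress genes past 2-fold (median 0.27). ABCC1 was at 1.11, ABCC4 at -1.02, TYMS at -0.07, SLC19A1 at 0.22, FPGS at -0.10, GGH at -0.49, ABCG2 at 0.30 and MSH3 at -0.32. COL3A1 was at 1.40 and FAS at -1.16, and without probe sets that can take signal from related transcripts they were at -0.30 and 0.07. The proliferation median was -0.07, DNA repair -0.08, WNT and TGF-beta genes 0.19 and leukocyte markers -0.02.

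**Figure D2:**
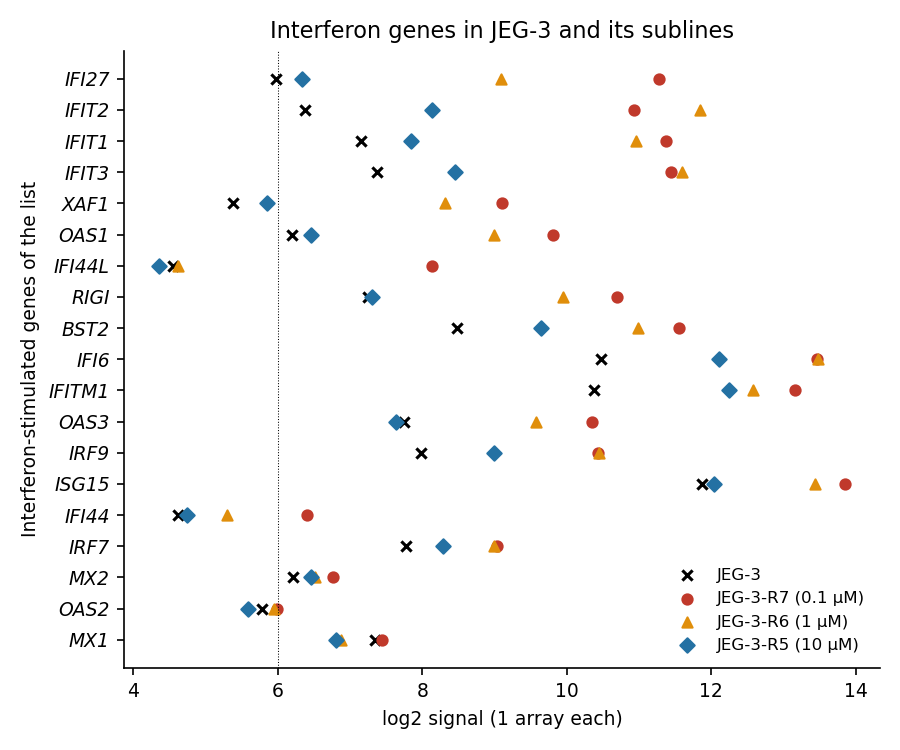
Log2 signal (horizontal axis) of interferon response genes (vertical axis) in JEG-3 and its 3 sublines, with 1 array and 1 symbol shape each and a dotted line at the signal floor of 6. The list median stood 2.98 above JEG-3 in JEG-3-R7, 2.48 above it in JEG-3-R6 and 0.37 above it in JEG-3-R5.

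**Figure D3:**
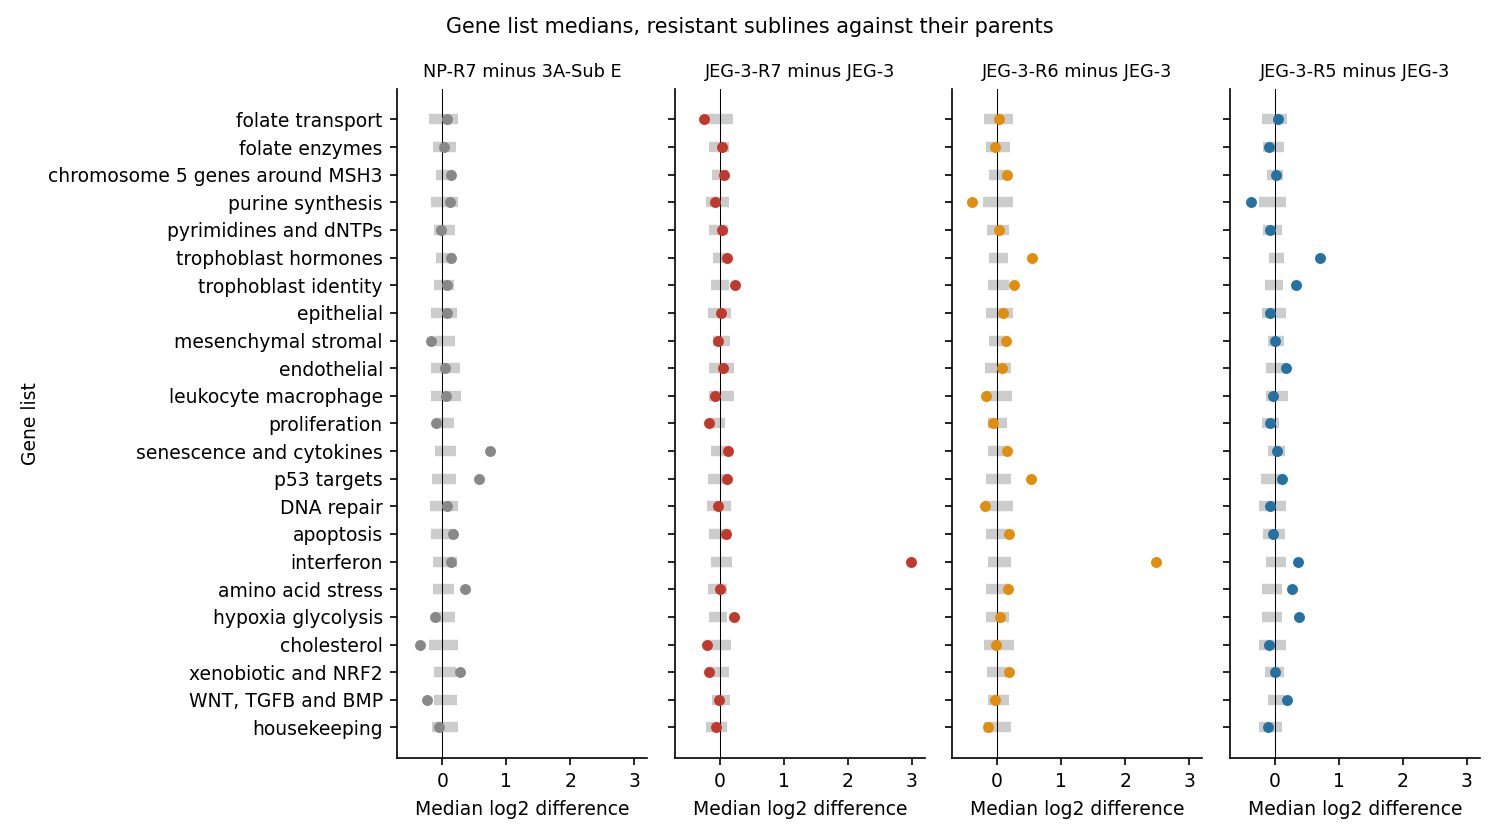
Median log2 difference (horizontal axis) of each fixed gene list (vertical axis) in each subline against its parent, 1 array each. Points are the medians and grey bars the middle 95% of 10000 random lists matched on mean expression, and the interferon list stands at 2.98 in JEG-3-R7 and 2.48 in JEG-3-R6.

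The sublines were then compared step by step, to follow the selection from JEG-3-R7 to JEG-3-R5. From JEG-3-R7 to JEG-3-R6 the imprinted gene PHLDA2 (3.28), S100A7 (2.59), PSG5 (2.58) and SNAI2 (2.35) were higher. IFI44L (-3.52), RASGRF2 (-3.42), CKMT2-AS1 (-3.20), CKMT2 (-3.08), MSH3 (-2.57) and IFI27 (-2.19) were lower, and 231 genes were higher and 65 lower in all. From JEG-3-R6 to JEG-3-R5 FZD10 (3.22), MGST1 (2.59) and MAGEA6 (2.59) were higher and CARD16 (-4.19), IFIT2 (-3.72), MARCKS (-3.67), CDKN2B (-3.61) and COL3A1 (-3.52) were lower, and 71 genes higher against 382 lower. Of the 16 genes furthest apart at each step, the dimmer array was below 6 for 4 and then 5. Other probe sets above the floor moved far less for PHLDA2 (0.0) and PSG5 (0.18) at the step to JEG-3-R6. The same held for CDKN2B (-0.1) at the step to JEG-3-R5. The interferon list had 0 higher and 3 lower at the step to JEG-3-R6 (median -0.56) and 0 higher and 12 lower of 16 at the step to JEG-3-R5 (median -1.40). Hormone genes had 10 higher and 0 lower at the step to JEG-3-R6 (median 0.35), and 1 higher and 1 lower at the step to JEG-3-R5 (median -0.24, percentile 0.07).

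Some genes moved one way at every step. Of 14641 genes, 1242 did so at any size, which is 8.5%, against 8.3% for 4 independent values and 25% for 3 independent steps. With a total of 2-fold or more, 69 were rising in order and 23 falling. MME (2.53), ERVFRD-1 (2.28), DOCK4 (2.28), SH3TC2 (2.08) and the keratin gene KRT23 (2.08) led the first group. HAND1 (-2.79), LPP (-1.61), SPA17 (-1.50), MARS2 (-1.37) and PDZRN3 (-1.35) led the second. ABCC1 was at 9.66 in JEG-3 and at 10.63, 10.68 and 10.77 in its sublines, in order of drug level. Its steps between sublines were no more than 0.1. The other ABCC1 probe set above the floor stood above JEG-3 by 0.64 in JEG-3-R7, 0.47 in JEG-3-R6 and 0.85 in JEG-3-R5. That probe set does not follow the drug level. With the mean of all probe sets, 54 genes in place of 92 met this rule. Of the 6 orders of the sublines after JEG-3, the order JEG-3-R5, JEG-3-R7, JEG-3-R6 gave the most such genes, 334. It draws on the 763 of these 14641 genes that were 2-fold apart between JEG-3 and its last array. The labelled order gave 92 of 312 (29.5%), which is a smaller share as well as a smaller count. The 14641 genes reach a log2 signal of 6 on at least 1 of the 4 JEG-3 arrays, so these totals differ slightly from those of the pairs.

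JEG-3-R7 and JEG-3-R6 had 276 genes higher in common, against 25.4 in simulated unchanged sublines that share the parental array and 14.8 for independent lists, and 52 lower in common (26.4 and 1.1). JEG-3-R7 and JEG-3-R5 had 100 higher in common (25.7 and 5.1) and 28 lower (24.8 and 0.8), and JEG-3-R6 and JEG-3-R5 had 159 higher (25.3 and 9.2) and 27 lower (24.2 and 0.7). The lower counts of these last pairs are close to those of simulated unchanged sublines. The simulated spread was taken from the limma fit and holds differences among the sublines, so it may be too wide. Closeness to it therefore cannot show that these genes are shared by chance alone. The covariance of their differences across genes was 0.170, 0.098 and 0.117, against 0.057, 0.056 and 0.056 in the simulation. Part of the excess over the independent lists may come from the shared parental array.

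Resistance to 0.1 µM was compared between NP-R7 and JEG-3-R7, each against its own parent, since these pairs share no array. Both sublines had RGS2 higher, by 2.49 in NP-R7 and 2.0 in JEG-3-R7. The lysosomal gene LAMP3 stood at 1.78 and 2.37, CREBRF, a regulator of the CREB3 stress response, at 1.46 and 1.5, and JAG1, a Notch ligand, at 2.42 and 1.42. MEIOC (2.23 and 1.41), YPEL2 (1.36 and 1.46), SAMD9 (1.36 and 2.95) and CARD16 (1.34 and 4.4) were also higher in both. DIO2, the deiodinase that activates thyroid hormone, was lower in both (-3.11 and -1.29), as were LINC00622 (-1.96 and -1.16), DPF3 (-1.43 and -1.11), ZNF232-AS1 (-1.06 and -1.33) and NCOA5 (-1.03 and -1.03). COL3A1 went opposite ways, at -2.33 and 4.84.

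Of 13559 genes, 31 were 2-fold or more higher in both against 6.0 for independent lists, 5 were lower in both against 1.6, and 13 went opposite ways against 6.7. Across genes, which are not replicates, the correlation of the differences was r = 0.073 (rho 0.071). With the mean of all probe sets the 36 genes that went the same way numbered 19.

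In the limma fit of all 6 arrays with cell line as a block, 0 genes differed between resistant and parental arrays at an adjusted p under 0.05, and 1310 of 15214 had an unadjusted p under 0.05. The lowest p was that of CREBRF, at 1.52 (SE 0.14, limma adjusted p = 0.387). SOCS1, an inhibitor of cytokine signalling (1.25), PROCR (1.09), the carbonic anhydrase CA12 (1.65), RIPOR2 (1.47), the cyclin gene CCNG2 (1.08) and RGS2 (2.46) followed. On the lower side were the ribosome assembly gene RRS1 (-1.12), NCOA5 (-0.99), the mitochondrial transcription factor TFAM (-0.69), the splicing factors SRSF3 (-0.43) and TRA2B (-0.52) and SFPQ (-0.79). Adjusted over the list alone, 1 epithelial gene, 2 p53 targets and 2 amino acid stress genes were higher and 1 cholesterol gene was lower, against 0 over all genes. Named after their values were seen, these were ELF3 (1.30), GDF15 (1.25), DDB2 (1.16), DDIT3 (0.87), HERPUD1 (0.65) and NSDHL (-0.73). The sublines of JEG-3 are not independent, so these p-values are too small, and without the JEG-3 parent array 71 genes were higher and 31 lower.

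The difference between the lines in their response was tested with the product of cell line and resistance. It took 14 genes past an adjusted p of 0.05 with limma, 3 with a higher and 11 with a lower effect in JEG-3, and 1247 had an unadjusted p under 0.05. CXCL5 had the lowest p, with the JEG-3 effect minus the placental effect at -5.97 (SE 0.27, limma adjusted p = 0.0164). The cytokine and chemokine genes IL1A (-4.76), CXCL1 (-4.45), CCL2 (-3.53) and CCL20 (-3.29), the protease MMP3 (-3.62), NAP1L3 (-5.10), SOX7 (-4.36), LINC00973 (-3.36) and the glycosyltransferase GALNT12 (-3.14) were lower as well, and 1 further gene has no characterised name. MSTN (4.72), VCAM1 (4.43) and SCN9A (3.09) were higher. In the senescence and cytokine list 4 genes were lower over all genes tested, and 1 was higher and 8 lower adjusted over the list alone. The named genes were below a log2 signal of 6 on every JEG-3 array, so their values mainly restate the difference of NP-R7 from 3A-Sub E. The spread comes from the 3 JEG-3 sublines, so the p-values are too small. The count was 0 without JEG-3-R7, 5 without JEG-3-R6 and 1 without JEG-3-R5, and between 2 and 52 under other settings.

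**Figure D4:**
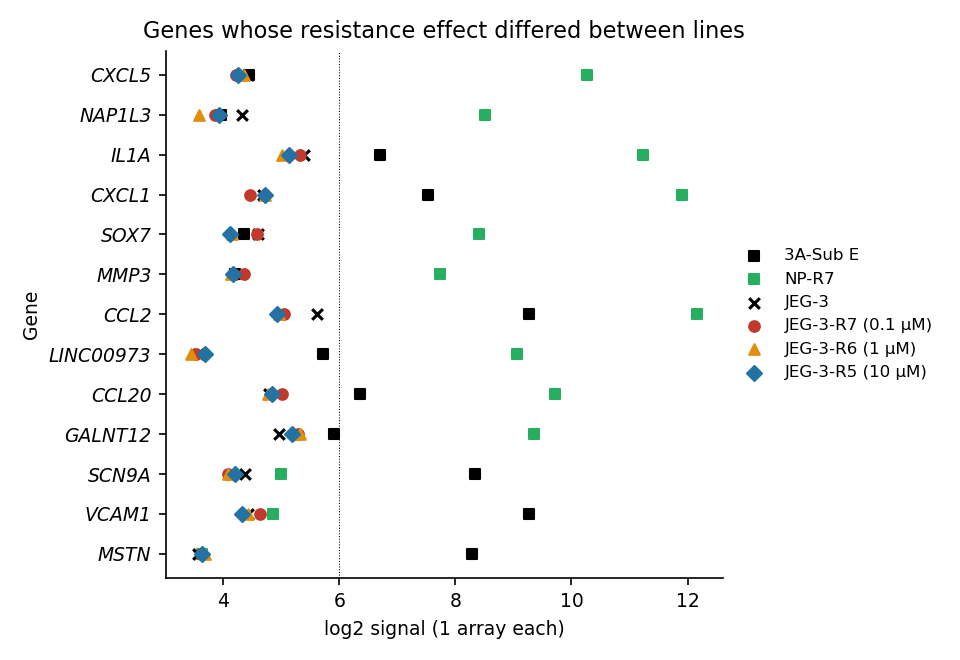
Log2 signal (horizontal axis) on each of the 6 arrays of the named genes whose resistance effect differed between the lines in the limma fit (vertical axis), with a dotted line at the signal floor of 6. CXCL5 was at 4.44 in 3A-Sub E and 10.26 in NP-R7, and all 13 named genes lie below 6 on the 4 JEG-3 arrays.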

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

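The tests of single probe sets and of copy number on chromosome 5, of scaling between arrays and of the order of the subline labels, and the counts over other choices of arrays, were chosen after the results were seen.

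In limma's test of the difference itself, the response to resistance differed between the lines in 14 genes, a count that depends on single arrays. It was 0 without JEG-3-R7, 5 without JEG-3-R6 and 1 without JEG-3-R5. The named genes lay below a log2 signal of 6 on every JEG-3 array, so for them the test mainly restates the difference of NP-R7 from 3A-Sub E. The placental line has 1 array on each side, so the p-values of this test are too small. Its values, the JEG-3 effect minus the placental effect, were 4.72 for MSTN, 4.43 for VCAM1, 3.09 for SCN9A, -5.97 for CXCL5, -4.76 for IL1A, -5.10 for NAP1L3, -4.45 for CXCL1, -3.53 for CCL2, -3.62 for MMP3, -3.14 for GALNT12, -3.29 for CCL20, -3.36 for LINC00973 and -4.36 for SOX7.

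Probe sets without a gene name, which the comparisons do not use, differed as well. In NP-R7, 52 of 4672 above the floor were 2-fold or more higher and 454 lower, and 1 was 8-fold or more higher. In JEG-3-R7, 63 of 4861 were higher and 46 lower, and 7 were 8-fold or more higher. In JEG-3-R6, 83 of 4782 were higher and 165 lower, and in JEG-3-R5 54 and 19 of 4896. Among named genes the counts were 395 higher and 268 lower of 14222 in NP-R7, 359 and 134 of 14377 in JEG-3-R7, 645 and 117 of 14392 in JEG-3-R6, and 228 and 82 of 14318 in JEG-3-R5, so the balance is reversed among unnamed probe sets in NP-R7 and JEG-3-R6, and the cause was not tested.

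On chromosome 5, the genes from MSH3 to ZCCHC9 were 2-fold or more higher in JEG-3-R7 and short of 2-fold in JEG-3-R6 and JEG-3-R5. A chance position of such genes is argued against by the shuffled gene orders (one-sided permutation p = 0.0002), and a single faulty probe by all 8 probe sets of these genes above the floor, which were 2-fold or more higher. At MSH3 this is weaker, since both of its probe sets (2.30 and 1.46) are marked as able to take signal from related transcripts. Cells of the placental line in the sample are argued against by a median in JEG-3-R7 of 0.11 for the genes bright in 3A-Sub E and dim in JEG-3, although 13 of these 123 (10.6%) were 2-fold or more higher against 2.5% of all genes, and by all 5 genes of the run, which stood above both parents, as no mixture can. A gain of copies of this stretch may be the source, with the nearest genes on either side that reach a log2 signal of 6 on some array at no more than 0.49, and the exact edge observed on neither side. No DNA was measured, so it stays open, as does regulation shared by these genes.

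Interferon genes and COL3A1 were far higher in JEG-3-R7 and JEG-3-R6 than in JEG-3-R5. Cells of the placental line, rich in COL3A1, are argued against by a median of 0.09 in JEG-3-R6 for the genes bright in 3A-Sub E and dim in JEG-3, although 18 of these 123 (14.6%) were 2-fold or more higher against 4.5% of all genes, and by 12 of the 14 interferon genes 2-fold or more higher, which stood above both parents. Scaling between arrays is argued against by random lists matched on mean expression, which it would move as well, and whose middle 95% ended at 0.22 against the list median of 2.48. Subline labels out of order cannot be told apart from a response that is lost late in selection, since 92 of 312 genes 2-fold from JEG-3 on the last array move one way in the labelled order and 334 of 763 in the order JEG-3-R5, JEG-3-R7, JEG-3-R6, and expression need not follow selection. An interferon response that differed between the cultures on the day of harvest may also be the source and was not tested.

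In NP-R7, 9 of 19 members of the senescence and cytokine list were 2-fold or more higher than in 3A-Sub E, all of them cytokine or protease genes and none a cyclin-dependent kinase inhibitor. Leukocytes in the culture are argued against by the median of the leukocyte and macrophage markers, 0.06 over 9 measured genes, of which the brightest in 3A-Sub E, CD14, was at 8.35 there and 7.33 in NP-R7 (-1.02). Scaling between arrays is argued against by random lists matched on mean expression, whose middle 95% ended at 0.22 against the list median of 0.75. The source stays open, since culture density and passage were not tested and a single array stands on each side.

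For the resistance term, all 8 choices of a parental array from each line gave 0 genes, the real one and the highest of the others included, so every choice ties and the count tells nothing. For the cell line term, 1 of the 14 choices of 2 arrays for which a fit exists gave as many genes, the real one, with 5955 genes against 0 for the highest other. In both cases the choices are too few for a share under 0.05.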

How the results depend on the processing

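All alternatives were planned, and none was chosen after the result was seen. Apart from the fits with cell line as a block, which set sublines against the parent of their own line, no paired analysis was possible because the labels give no replicate numbers. With no signal floor, a floor of 7, cyclic loess, or without probe sets that can take signal from related transcripts, all 7 counts from pairs of arrays stayed within 1.5 times. At 3-fold they were 2181 for the parents, 200 for NP-R7, 157 for JEG-3-R7, 279 for JEG-3-R6, 54 for JEG-3-R5, 16 for genes moving one way through the selection and 2 for both lines, fewer by construction. With the mean of all probe sets of a gene, counts were 196 for JEG-3-R5, 54 for the selection steps, 19 for both lines and 35 for the difference between lines. List medians were then 2.11 for interferon genes in JEG-3-R6 and 3.51, -3.18 and 3.19 for epithelial, mesenchymal and trophoblast identity genes between the parents, and the cause was not tested. The count for the difference between lines was 2 at a mean signal of 6 or more, 52 with no filter, 6 with eBayes without trend and 6 after cyclic loess, and the cause was not tested. The resistance term gave 0 genes under every alternative that kept all 6 arrays, with the JEG-3 arrays alone and with the parents and 0.1 µM sublines alone. Leaving out each array in turn, it gave 0 to 102 genes (102 without the JEG-3 parent), the cell line term 3477 to 5576, and the difference between lines 0 to 5. For the latter, leaving out the JEG-3 parent or either placental array gave no estimate. A lone array was assumed to vary like the others. With members above the floor only, all 15 list medians tried moved by no more than 0.27, the margin set for list medians. The interferon median in JEG-3-R5 went from 0.37 to 0.51 and the hormone median in JEG-3-R6 from 0.54 to 0.67. The cholesterol median in NP-R7 stayed at -0.34. For medians this small the margin is wide, so passing it tells little about their size. Of the 271 named differences all kept their size after cyclic loess, and with the mean of all probe sets 147 did, 124 moved and 0 reversed. Without probe sets that can take signal from related transcripts, 170 of 219 did, 44 moved and 5 reversed. These were ADGRL2 (-0.18) and SMAD6 (0.17) in NP-R7, DHFR2 (-0.81) in JEG-3-R7, and COL3A1 (-0.30) and FAS (0.07) in JEG-3-R5, and the cause was not tested. Genes near the signal floor of 6 are the least certain.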

Other observations

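The tests over windows of neighbouring genes and the gene families, zinc finger genes included, were chosen after the results were seen. What low signal would give for the zinc finger genes was written down before its test, but for a family already picked from these arrays. The place of these families among random lists therefore describes these arrays and is no independent test.

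Zinc finger genes of chromosome 19, a large class of transcriptional repressors, had a median below 0 in NP-R7 and above 0 in the JEG-3 sublines, and most of them did not pass 2-fold. In NP-R7, 0 were 2-fold or more higher and 24 lower of 154 above the floor (median -0.34). In JEG-3-R7, 8 were higher and 0 lower of 167 (median 0.17), in JEG-3-R6 22 and 0 of 169, and in JEG-3-R5 4 and 0 of 161 (median 0.12). Zinc finger genes of other chromosomes had medians of -0.07, 0.01, 0.06 and 0.02, and that of NP-R7 was also outside its random lists (-0.01 to 0.09). Low signal of these genes as the source is argued against by the median of 0.29 in JEG-3-R6, outside the middle 95% of random lists matched on mean expression, -0.04 to 0.06. The difference between the lines was not tested for this family.

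Pregnancy-specific glycoprotein genes, secreted by the placenta and placed side by side on chromosome 19, formed runs of genes that were 2-fold or more higher. The longest run in JEG-3-R6 held 5 genes from CEACAM1 to PSG7 (one-sided permutation p = 0.003), and that in JEG-3-R5 held 4 from PSG2 to PSG9 (one-sided permutation p = 0.0008). The longest run in NP-R7, from LAMB3 to HSD11B1 on chromosome 1, held 3 (one-sided permutation p = 0.2). The cancer-testis MAGEA genes of chromosome X had medians of -0.68, -0.48 and -0.43 in the JEG-3 sublines, in order of drug level. Of 6 above the floor, 1 was 2-fold or more higher and 3 lower in JEG-3-R7, the same in JEG-3-R6, and 0 and 1 in JEG-3-R5. Both families are of near-identical copies whose probe sets can share signal.

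Windows of 25 neighbouring genes shifted together in each of the 6 comparisons tried. The window furthest from 0 had a median of -0.66 in NP-R7 (SIGLEC6 to ZNF468, chromosome 19), -0.65 in JEG-3-R7 (RBAK to RPA3, chromosome 7) and 0.69 in JEG-3-R6 (DEDD2 to ETHE1, chromosome 19). From JEG-3-R7 to JEG-3-R6 the window from WIPI2 to GLCCI1 on chromosome 7 had a median of 0.82. The chromosome 19 window of JEG-3-R6 may hold the pregnancy-specific glycoprotein genes above, whose probe sets can share signal. Both chromosome 7 windows may overlap each other. These windows are therefore not to be read as separate observations. The highest of the 6 permutation p was 0.001, also after Benjamini-Hochberg adjustment, which is the smallest that 1000 shuffles can give.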
